A study of Rattus norvegicus with 40 samples.

How the data were processed

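Total RNA of the rat glial precursor line CG4 carrying the erythropoietin receptor was hybridised to 40 1-colour (Cy3) expression arrays on 5 slides of 8 arrays, each scanned 1 time. The labels place the arrays in 11 groups: undifferentiated cells, and cells differentiating for 1 h or 20 h as untreated control, with erythropoietin (EPO, 10 ng/ml), with leukemia inhibitory factor (LIF) at 10 ng/ml, with LIF at the lower dose of 0.2 ng/ml, or with EPO and LIF together (10 ng/ml each). The group labelled as low LIF was taken as the 0.2 ng/ml dose because both doses appear in the labels. Per the labels, RNA was extracted with QIAzol and a miRNeasy kit. Group sizes were 3 (undifferentiated, LIF 0.2 at 1 h and 20 h, LIF 10 at 20 h) or 4 (all other groups).

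The deposited array files hold intensity values: per the file headers they came from Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09, and probe positions refer to build rn4. The processed signal in these files is background-subtracted and detrended within the array, with a surrogate value for dim spots, and is not normalized between arrays. Beside these files the authors deposited a value table of log2 values without stating its steps. All of its columns matched the log2 processed signal after subtraction of each array's 75th percentile and of each probe's median, with a lowest correlation of 0.999978 and a median absolute difference of 0.00264. Column medians in that table ran from −0.16 to 0.22.

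The values used here were the log2 processed signal, averaged over the spots of a probe, minus the 75th percentile of the array. Of 58717 non-control spots, 30367 probes resulted. They were named from their RefSeq accession (18643 probes), symbol (3403) or synonym (393) in the annotation table, and 7928 kept the name in the file. These are 25885 genes or other names, each represented by its probe with the highest mean over the 40 arrays. Genes were tested when the probe was well above background, by the flag of the extraction software, on every array of at least 1 of the 11 groups, which left 15264 genes. Of the probe values, 51 were missing and 0 were saturated.

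Arrays differed in the 75th percentile of their processed signal from 628.7 to 1142, in their median signal from 63.4 to 126.2, and in the share of probes well above background from 55.3% to 59.9%. At most 1.62% of the spots of an array were flagged by the software. The number of arrays limits the precision of every fold.

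Differences were tested with limma 3.58.1 in R 4.3.3, as contrasts of 11 group means fitted to all 40 arrays with no block, with p-values adjusted over the 15264 genes by Benjamini-Hochberg and a threshold of 0.05. All tests are 2-sided. Adjusted p-values in the text come from this model unless another setting is named, and ± after a fold is its standard error. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. There were 20 comparisons: both control times against undifferentiated cells; EPO, each LIF dose and EPO+LIF against control at each time; EPO+LIF against EPO and against LIF 10 at each time; LIF 10 against LIF 0.2 at each time; the EPO by LIF interaction (EPO+LIF minus EPO minus LIF 10 plus control) at each time; and the EPO and LIF 10 effects at 20 h minus those at 1 h.

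A gene of which no array in a group was well above background is called near background in that group. Its level there was raised on each array to the lowest signal well above background, and the fold is given as "at least". Such bounds differ from the fitted log2 folds, which the tests use. No fold is given where both groups were near background.

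The 14 gene lists, 17 genes to be named in every case (Mog and Osmr, which are among them, did not pass the filter), the comparisons, the main settings and most alternatives were fixed before the data were examined. Genes named in the text follow a rule fixed at the same time. The rule took, among genes with a symbol, an adjusted p under 0.05 and arrays that do not overlap between both groups, the 10 largest rises and the 10 largest falls (5 and 5 in secondary comparisons). It added up to 4 members of each list described, those with the smallest p in each direction, and the 17 genes. The text gives a part of the genes the rule took. 4 listed members (Nkx2-2, Nlrc5, Hspa1a and Rbfox3) were not found on the array. For each list the counts of genes that rose or fell are given over all genes tested and adjusted over the list alone. Each list was compared with all other genes by camera (limma), with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 14 lists of a comparison.

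2 properties of the arrays were examined as possible batches. Slides 3, 4 and 5 each hold 1 array of control, EPO, LIF 10 and EPO+LIF at both times, and slides 1 and 2 hold the remaining arrays. The spike-in RNAs split the arrays at a dose-response slope of 0.9 into 12 low-slope arrays (0.648 to 0.757) and 28 high-slope arrays (1.012 to 1.044). The 12 are all of control and EPO at 1 h, 2 of 4 of LIF 10 at 1 h and 2 of 3 of LIF 0.2 at 1 h. This split, called the spike-in set below, was found in the data, and the fits with it as a fixed block were chosen after that. LIF 10 and LIF 0.2 at 1 h hold arrays of both sets and so carry the estimate of the set difference.

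Whether replicate numbers pair samples was checked once, by the correlation of the deviations from the group means of same-numbered arrays in 16 comparisons. The numbers come from the labels. Of 55 pairs, 31 correlated above 0.1, and every pair did so in 3 comparisons (LIF 10 vs control, EPO+LIF vs EPO and EPO+LIF vs LIF 10, all at 20 h). The unpaired fit was kept as the main one.

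Alternatives were the authors' value table, quantile normalization, a normexp background correction with an offset of 50 on the raw signals, no filter on dim probes, a filter asking for all 40 arrays, the mean of a gene's probes, a replicate block, the slide as a fixed or random block, a fit of the compared groups alone, and leaving out each array in turn. Chosen after seeing the data were the spike-in set as a block, that block with the replicate block, fits of the low-slope or high-slope arrays alone, and leaving out the 2 arrays farthest out on the second principal component. A count was called different beyond a ratio of 1.5. Groupings of the arrays other than the real one were fitted in full where they numbered 35 or fewer, and 100 seeded reassignments of the residuals from the additive fit were drawn for interactions and time differences. Outlying arrays in groups of 4 were sought with Dixon's ratio above 0.829. Of the genes chosen in advance to be named, 1 is not reported here, and it was left out of this search and of the named time differences after they had first been run.

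The scripts were tested on simulated data, drawn from a normal distribution with each gene's mean and within-group SD, in which 200 genes were changed. At a simulated log2 change of 1, 86.6% of changed genes were called in the right direction for EPO at 20 h, 80.6% for LIF 10 at 20 h, 88.1% for EPO at 1 h and 76.1% for the interaction at 20 h, and 2.4% to 5.0% of the calls were false. With a simulated spike-in set effect on 2000 genes, 1981 of them were called for EPO+LIF vs control at 1 h without the block and 1 with it, while called genes among 200 with a treatment effect went from 197 to 186. Of 100 simulated lists with members raised by 0.3, 100 were called upward, and of 100 unchanged lists 8 had a p under 0.05. The simulation left out correlation between genes and spread of the set effect between low-slope arrays, so block and camera were not tested for these.

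Further tools were statmod 1.5.0, version 1.17.8 of the R package data.table, Python 3.11.15 and matplotlib 3.10.9. Control spots other than the spike-ins were left out. Probes below the filter were left out except where an alternative restores them. No reference genome was used, because positions were taken from the array files.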

Results

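Transcript levels were measured on 40 arrays of a rat oligodendrocyte precursor line, CG4 cells carrying the EPO receptor, with 3 arrays of undifferentiated cells and 37 of cells differentiating for 1 h or 20 h. Differentiating cells were untreated (control) or received EPO, LIF at 0.2 or 10 ng/ml (LIF 0.2 and LIF 10), or EPO and LIF together (EPO+LIF), with 3 or 4 arrays per group. Per array 55.3% to 59.9% of probes were well above background, and within groups arrays correlated at 0.9832 or above. Levels are log2 signal over the array's 75th percentile and folds are log2 differences ± SE. A normexp background correction shrinks the folds of dim genes by its construction, and it is named below where it ended the call of a named gene.

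The Epor probe (8:21061326-21061385) lay at −4.17 ± 0.207 (SD, n = 3) in undifferentiated cells. In control cells it lay at −6.41 ± 0.423 at 1 h and −3.18 ± 0.185 at 20 h (SD, n = 4 each). At 1 h it was well above background on 1 of 4 arrays. Whether it reads the receptor the line carries was not tested. Lifr, the LIF receptor, lay near background in many arrays, with group means from −6.85 to −5.30. Il6st, the signal-transducing subunit shared by receptors of the LIF family, was well above background on every array, with group means from −0.10 to 0.71. The 12 arrays with a low spike-in slope, all taken at 1 h, carried higher levels of 11 of 31 listed keratinocyte transcripts than the 7 other 1 h arrays, by more than 2 log2 units each. Among them, Krt17 differed by 8.54 and Krt10 by 8.05, with both near background on the 7 arrays, so these folds are not exact. Krt14 differed by −0.43. The 12 hold all control and EPO arrays at 1 h, 2 of 4 LIF 10 and 2 of 3 LIF 0.2 arrays. They hold no EPO+LIF or undifferentiated array.

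**Figure D1:**
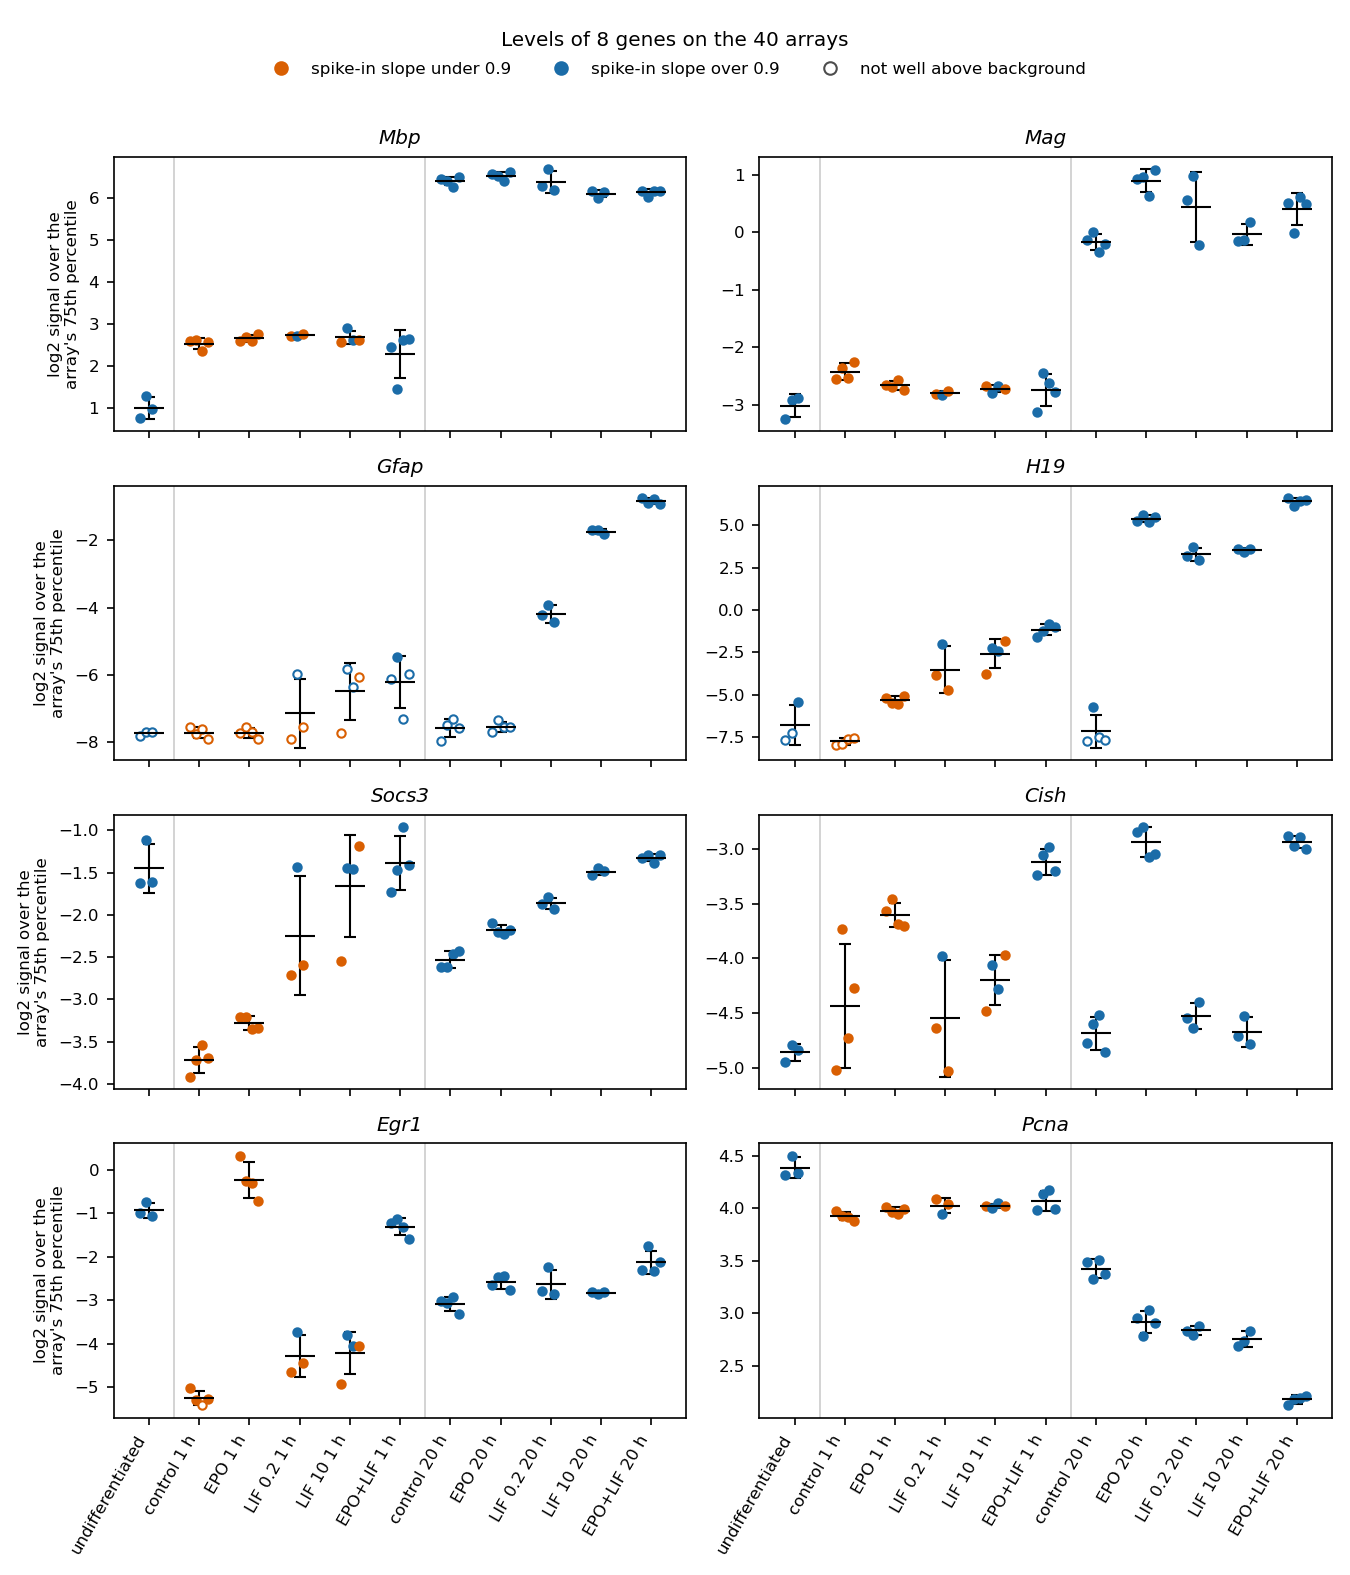
Levels of 8 genes on each of the 40 arrays by group, as log2 signal over the array's 75th percentile, with the group mean ± SD as bars (n = 3 or 4 arrays); orange points have a low spike-in slope, blue points a high one, and open points were not well above background. Mbp was highest in the 20 h groups, with means between 6.11 and 6.55, and Gfap was well above background in the LIF groups at 20 h and on 1 array of EPO+LIF at 1 h.

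**Figure D2:**
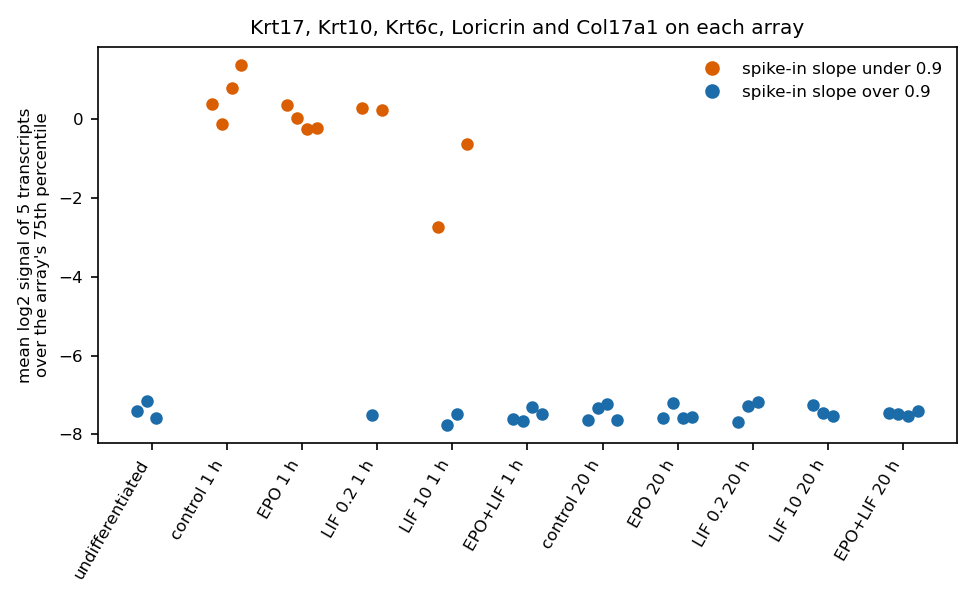
Mean log2 level of 5 keratinocyte transcripts (Krt17, Krt10, Krt6c, Loricrin and Col17a1) over the array's 75th percentile, with 1 point per array by group and colour by spike-in slope. Within the LIF 10 and LIF 0.2 groups at 1 h, the lowest low-slope array lies 4.741 log2 units above the highest high-slope array.

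The first hour of differentiation was compared with the undifferentiated state (4 and 3 arrays). Egr1, an immediate early transcription factor, fell by −4.32 ± 0.22 (adjusted p = 2.31e-16), and Spry4 (18:31532750-31532809), a feedback inhibitor of receptor tyrosine kinase signalling, by −4.58 ± 0.18 (adjusted p = 2.94e-19; −2.743 with the mean of its probes). Mbp (18:79057264-79057323), which encodes myelin basic protein, rose by 1.54 ± 0.17 (adjusted p = 9.35e-09). Pdgfra and Cspg4, markers of precursors, fell by 0.97 (adjusted p = 2.46e-11) and −1.44 (adjusted p = 1.75e-06). Epor fell by 2.24 ± 0.25 (adjusted p = 1.1e-08), a fold that is not exact. Of 24 cholesterol synthesis genes 0 rose and 23 fell, also when adjusted over the list alone (camera adjusted p = 3.38e-16), with Sc5d at −1.30 ± 0.08 as an example. Immediate early genes rose in 5 and fell in 19 of 27 cases (the same counts adjusted over the list alone; camera adjusted p = 4.48e-12). Stress response genes rose in 2 and fell in 12 of 18 cases (also adjusted over the list alone; camera adjusted p = 3.76e-14), Atf4 by −1.42 ± 0.06. Precursor genes rose in 1 and fell in 14 of 21 cases (also adjusted over the list alone; camera adjusted p = 7.24e-07), and myelin genes rose in 10 and fell in 1 of 19 cases (11 and 1 adjusted over the list alone; camera adjusted p = 0.000214).

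Across the 15264 genes tested between these groups, 2871 rose and 2739 fell (limma), and groups did not overlap for 30% of all genes (5.71% by chance), 4095 of the 5610 among them. With the spike-in set as a block 3308 were called, 2870 of them in both fits in the same direction; the blocked folds were −3.66 for Egr1, −4.07 for Spry4, 1.63 for Mbp, −0.73 for Pdgfra and −2.41 for Epor. The keratinocyte transcripts Krt6c and Krt10, which were at least 366-fold and 213-fold higher, differed by 1.91 and 0.97 with this block. Fitting these groups alone called 1962 genes.

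After 20 h of differentiation without cytokines, compared with the undifferentiated state (4 and 3 arrays), myelin genes had risen and cell cycle genes had fallen. Mbp rose by 5.42 ± 0.17 (adjusted p = 1.15e-22) and Mag (1:85954601-85954660), a myelin-associated glycoprotein, by 2.85 ± 0.18 (adjusted p = 6.81e-15). Tnr (13:75347093-75347152), an extracellular matrix glycoprotein of oligodendrocytes, rose by 5.66 ± 0.12 (adjusted p = 1.02e-26). Adm (1:168382310-168382369), the precursor of the peptide adrenomedullin, rose by 6.36 ± 0.33 (adjusted p = 8.06e-17). Falls were seen in Slc7a11, a cystine transporter, by −4.69 ± 0.16, in Olig2, a lineage transcription factor, by −1.76 ± 0.11 (adjusted p = 5.05e-15), and in the neuropeptide precursor Tac1 (at least 17.4-fold). Pdgfra at −0.12 (adjusted p = 0.227) and Sox10 at 0.06 (adjusted p = 0.702) did not pass the test.

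Among the lists at 20 h, 15 of 19 myelin genes rose and 2 fell (also adjusted over the list alone; camera adjusted p = 3.5e-11), the falls being Gjb1 (−1.13) and Car2 (−0.995). Cell cycle genes rose in 0 and fell in 30 of 32 cases (also adjusted over the list alone; camera adjusted p = 1.14e-16), Pcna, a replication clamp, by −0.96 ± 0.06 (adjusted p = 1.3e-14). Hypoxia and glycolysis genes rose in 14 and fell in 1 of 18 cases (15 and 1 adjusted over the list alone; camera adjusted p = 2.78e-10), with Pdk1 at 2.66 and Aldoc at 2.20. Stress response genes rose in 1 and fell in 12 of 18 cases (also adjusted over the list alone; camera adjusted p = 3.94e-07). The cholesterol list shifted downward, with 1 gene up and 10 down of 24 in both counts (camera adjusted p = 0.0238; adjusted p = 0.333 with an estimated correlation). The acute phase and cytokine list, with 3 up and 4 down of 8 in both counts, had a camera adjusted p of 0.0158 (adjusted p = 0.154 with an estimated correlation and 0.0511 with quantile normalization). Precursor genes rose in 6 and fell in 11 of 21 cases, with a camera adjusted p of 0.664. Over all genes tested 4211 rose and 3661 fell, 1742 of them at least 2-fold, and groups did not overlap for 42.2% of all genes (5.71% by chance), 6038 of the called ones among them. Fitting these groups alone called 4526. Cnp, a myelin enzyme, rose by 1.06 (adjusted p = 0.00582), but by 0.55 (adjusted p = 0.135) without undifferentiated replicate 3, and had an adjusted p = 0.0607 in that fit. Without the same replicate the rise of Myrf, a myelin gene regulator, went from 1.34 to 0.79.

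EPO at 1 h, which asks for the early response to the receptor, raised few transcripts over control (4 arrays each). Egr1 (18:27347173-27347232) rose by 5.02 ± 0.20 (adjusted p = 5.18e-18) and Fos (6:109561941-109562000), another immediate early transcription factor, by 1.91 ± 0.18 (adjusted p = 4.55e-08). The small GTPase gene Arl4a rose by 0.91 ± 0.17 (adjusted p = 0.00768) and the homeobox gene Irx2 by 0.77 ± 0.10 (adjusted p = 1.64e-05). Of the immediate early list, 5 genes rose and 0 fell of 27 (8 and 0 adjusted over the list alone; camera adjusted p = 1.46e-28). JAK-STAT feedback genes rose in 1 and fell in 1 of 25 cases (camera adjusted p = 0.47), with Socs3, a cytokine feedback inhibitor, at 0.44 (adjusted p = 0.804). Genes that rose numbered 13 and those that fell 6, and groups did not overlap for these 19 and for 8.8% of all genes (2.86% by chance). Both groups lie in the low-slope spike-in set, and 32 genes were called with the set as a block and 53 with the slide as a block (13 up and 40 down). With normexp the share that rose was 32.1% in place of 68.4%.

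Some EPO calls at 1 h rested on a setting or an array. Cish, a STAT5 target and feedback inhibitor, rose by 0.83 ± 0.18 (adjusted p = 0.0473), but by 0.34 (adjusted p = 0.276) with normexp and 0.46 (adjusted p = 0.539) with the mean of its probes. Its adjusted p was 0.259 in a fit of these groups alone, 0.0636 without the filter on dim probes, and between 0.0643 (EPO replicate 1) and 0.299 (control replicate 4) when any array of both groups except control replicate 3 was left out. Spry4 rose by 1.27 ± 0.17 (adjusted p = 3.69e-05), and by 0.69 (adjusted p = 0.101) with the mean of its probes, with an adjusted p = 0.0913 in a fit of these groups alone. Bcl6, a transcriptional repressor, fell by 0.60 ± 0.10 (adjusted p = 0.00219; 0.109 in a fit of these groups alone). The number of called genes was 12 without control replicate 4, 10 without control replicate 2, 11 without control replicate 1 and 12 without EPO replicate 3.

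LIF 10 at 1 h was compared with control for the early response to LIF (4 arrays each). Fos rose by 4.61 ± 0.18 (adjusted p = 1.66e-18), Bcl3 (1:79122832-79122891), a nuclear IkB family protein, by 4.37 ± 0.43 (adjusted p = 8.05e-08), and Junb, an immediate early transcription factor, by 3.07 ± 0.33 (adjusted p = 2.51e-07). Socs3 (10:107958636-107958695) rose by 2.06 ± 0.21 (adjusted p = 1.28e-07), the receptor tyrosine kinase inhibitor Spry1 by 2.72 ± 0.26 (adjusted p = 4.4e-08) and the interferon regulatory factor Irf1 by 1.34 (adjusted p = 1.28e-07). H19 (1:202822987-202823046), an imprinted non-coding RNA, was at least 19.1-fold higher. Cish differed by 0.24 (adjusted p = 0.76). With the spike-in set as a block these folds were 4.26 for Fos, 3.36 for Bcl3, 2.36 for Junb, 1.69 for Socs3, 2.20 for Spry1, 1.05 for Irf1 and 4.59 for H19, each still called. The largest falls were keratinocyte transcripts, such as Krt6c at −5.89 and Loricrin at −5.37. These were −2.25 (adjusted p = 0.00158) and −2.71 (adjusted p = 0.00529) with the block, so both were still called, and a fit of these groups alone gave the same folds with adjusted p = 0.196 and 0.106. Of the LIF 10 arrays 2 of 4, and of the control arrays 4 of 4, are of the low-slope set.

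JAK-STAT feedback genes rose in 11 and fell in 3 of 25 cases after 1 h of LIF 10 (11 and 4 adjusted over the list alone; camera adjusted p = 1.63e-12), and in 8 and 1 cases with the set as a block. Immediate early genes rose in 7 and fell in 3 of 27 cases (9 and 3 adjusted over the list alone; camera adjusted p = 1.94e-11). The interferon list had 2 genes up and 0 down of 13 in both counts and a shift upward in the test, opposite in sign to its median of −0.02 (camera adjusted p = 0.0343; adjusted p = 0.265 with an estimated correlation and 0.0501 with the slide as a block). The cholesterol list had 0 of 24 genes called and a downward shift (camera adjusted p = 0.0239; adjusted p = 0.265 with an estimated correlation). The microglia list, with 0 up and 1 down of 8, and the stress list, with 0 up and 1 down of 18, also shifted downward (camera adjusted p = 0.0343 each; adjusted p = 0.184 each with an estimated correlation, 0.248 for the stress list with the set as a block, and 0.185 for the microglia list with quantile normalization). Altogether 160 genes rose and 187 fell, and 292 of them were among the 8.7% of all genes without overlap between the groups (2.86% by chance). The spike-in set block called 128 genes, 119 of them in both fits in the same direction, the slide block 391, and a fit of these groups alone 60. Without LIF 10 replicate 3 or replicate 2 the number was 193 or 196.

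LIF 0.2 at 1 h tested the lower dose against control (3 and 4 arrays). Fos rose by 4.17 ± 0.19 (adjusted p = 3.3e-16). Bcl3 rose by 3.06 ± 0.47 (adjusted p = 0.000557), Socs3 by 1.47 ± 0.23 (adjusted p = 0.000557) and Irf1 by 1.04 (adjusted p = 0.000326), although a fit of these groups alone gave adjusted p = 0.375 for Bcl3, 0.34 for Socs3 and 0.337 for Irf1. Of the JAK-STAT feedback list, 5 genes rose and 0 fell of 25 (9 and 0 adjusted over the list alone; camera adjusted p = 4.29e-11). Of the immediate early list, 4 genes rose and 0 fell of 27 (5 and 2 adjusted over the list alone; camera adjusted p = 4.64e-09; adjusted p = 0.0649 with an estimated correlation). The interferon list, with 1 up and 0 down of 13 (2 and 0 adjusted over the list alone), shifted upward (camera adjusted p = 0.00577), and the cholesterol list, with 0 of 24 called, downward (camera adjusted p = 3.66e-05), with an adjusted p = 0.0649 each with an estimated correlation. The neuron and precursor lists, with 0 of 12 and 0 of 21 genes called, had a camera adjusted p of 0.048 each (adjusted p = 0.179 each with an estimated correlation). The neuron list had an adjusted p = 0.115 with quantile normalization, and the precursor list 0.0746, 0.0752 and 0.167 with the spike-in set, replicate and slide as blocks.

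In this comparison 28 genes rose and 9 fell, all 37 without overlap between the groups, as for 11.3% of all genes (5.71% by chance); 1 slide holds both groups. The spike-in set block called 23 genes, 22 of them in both fits, with Fos at 3.94, Bcl3 at 2.39 and Socs3 at 1.22. A fit of both groups alone called 3 genes, and the share that rose was 59.4% with normexp in place of 75.7%. The number was 56 without LIF 0.2 replicate 4, 9 without LIF 0.2 replicate 2, and 18, 20 and 21 without control replicates 4, 2 and 1.

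EPO+LIF at 1 h was compared with control for the early response to both cytokines (4 arrays each). Fos rose by 4.80 ± 0.18 (adjusted p = 4.93e-19), Egr1 by 3.94 ± 0.20 (adjusted p = 3.32e-15), Bcl3 by 5.10 ± 0.43 (adjusted p = 9.26e-10) and Socs3 by 2.32 (adjusted p = 3.6e-09). H19 was at least 50.6-fold higher. Control and EPO+LIF differ wholly in spike-in set; with the set as a block Fos rose by 4.10, Egr1 by 3.28, Bcl3 by 3.08 and Socs3 by 1.58, and H19 by 5.40. Cish rose by 1.32 (adjusted p = 5.21e-06), by 0.784 with the mean of its probes, and had a fold of 0.94 (adjusted p = 0.129) with that block. Krt17 was at least 355-fold lower and Krt10 at least 187-fold lower, and they differed by −1.77 (adjusted p = 0.449) and −0.88 (adjusted p = 0.296) with the block. Immediate early genes rose in 13 and fell in 1 of 27 cases (14 and 2 adjusted over the list alone; camera adjusted p = 2.57e-21). The JAK-STAT feedback genes rose in 11 and fell in 3 of 25 (13 and 3 adjusted over the list alone; camera adjusted p = 4.82e-12). With the block the rises numbered 5 and 4 in these lists, with 0 falls in both.

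A total of 706 genes rose and 454 fell with EPO+LIF at 1 h, and 979 of them were among the 13% of all genes without overlap between the groups (2.86% by chance). The spike-in set block left 49 called, 41 of them in both fits in the same direction, while 1360 were called with the slide as a block. A fit of these groups alone called 415, and 718 were called without control replicate 2.

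Adding LIF to EPO at 1 h, EPO+LIF against EPO alone (4 arrays each), raised Bcl3 by 4.83 ± 0.43 (adjusted p = 9.12e-09), Fos by 2.89 (adjusted p = 1.49e-12) and Irf1 by 1.51 (adjusted p = 1.02e-08). With the spike-in set as a block, which differs wholly between these groups, Bcl3 rose by 2.80, Fos by 2.19 and Irf1 by 0.93. Socs3 rose by 1.89, and by 1.15 (adjusted p = 0.12) with the block. Krt17 was at least 211-fold lower and Krt10 at least 152-fold lower with EPO+LIF, against −1.02 and −0.58 (adjusted p = 1 each) with the block. JAK-STAT feedback genes rose in 12 and fell in 3 of 25 cases (14 and 3 adjusted over the list alone; camera adjusted p = 5.82e-11; adjusted p = 0.0511 with an estimated correlation). Of the immediate early list, 8 genes rose and 4 fell of 27 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00184). Cholesterol genes rose in 6 and fell in 0 of 24 (10 and 0 adjusted over the list alone; camera adjusted p = 0.00373). Both lists had an adjusted p = 0.406 with an estimated correlation, and the immediate early list one of 0.0684 with the spike-in set as a block. Genes that rose numbered 490 and those that fell 239, 648 of them without overlap between the groups, as for 12.8% of all genes (2.86% by chance). Only 11 were called with the spike-in set as a block, all 11 also without it, and 952 with the slide as a block. The share that rose was 80.1% with normexp in place of 67.2%, a fit of these groups alone called 298 genes, and 473 and 462 were called without replicate 2 of EPO or of EPO+LIF.

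Adding EPO to LIF 10 at 1 h (4 arrays each) raised Egr1 by 2.90 ± 0.20 (adjusted p = 4.19e-11), and by 2.56 with the spike-in set as a block. Spry4 rose by 1.27 (adjusted p = 6.39e-05), Csrnp1, an immediate early gene, by 1.35 (adjusted p = 6.58e-05; 0.778 with the mean of its probes) and Cish by 1.08 ± 0.18 (adjusted p = 0.00178; 0.0615 with that block), while Bcl6 fell by 0.72 ± 0.10 (adjusted p = 8.91e-05). Immediate early genes rose in 3 and fell in 0 of 27 cases (8 and 0 adjusted over the list alone; camera adjusted p = 2.88e-12). Cholesterol genes rose in 2 and fell in 0 of 24 (9 and 0 adjusted over the list alone; camera adjusted p = 2.88e-08). Of the JAK-STAT feedback list, 1 gene rose and 1 fell of 25 (4 and 2 adjusted over the list alone; camera adjusted p = 0.014; adjusted p = 0.298 with an estimated correlation and 0.309 with the spike-in set as a block). Upward shifts in the precursor list, with 0 of 21 genes called (camera adjusted p = 0.00374), and in the stress list, with 1 up and 0 down of 18 (3 and 0 adjusted over the list alone; camera adjusted p = 0.00465; mean −0.02, median 0.09), had an adjusted p = 0.0896 each with an estimated correlation. In all 30 genes rose and 6 fell, every one without overlap between the groups, as for 3.6% of all genes (2.86% by chance). With the set as a block 18 were called, 14 of them in both fits, and 50 with the slide as a block. A fit of these groups alone called 1, which was Egr1, and gave adjusted p = 0.561 for Spry4 and Bcl6, 0.566 for Csrnp1 and 0.186 for Cish (0.0582 from the high-slope arrays alone). With the mean of its probes Spry4 had a fold of 0.73 (adjusted p = 0.0532). The number was 19, 23 and 20 without LIF 10 replicates 4, 3 and 1, and 22 and 69 without EPO+LIF replicates 2 and 1.

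LIF 10 and LIF 0.2 at 1 h (4 and 3 arrays) differed in 2 genes. Syt17, a synaptotagmin family member, was at least 2.02-fold higher and the carboxylesterase Ces2b at least 7.9-fold lower at the higher dose, without overlap between the groups; over all genes tested, 2.6% had no overlap, against 5.71% by chance. Socs3 differed by 0.59 (adjusted p = 1). Upward shifts in the JAK-STAT list (0 of 25 genes called; camera adjusted p = 0.0409), the immediate early list (0 of 27; camera adjusted p = 0.0324) and the neuron list (0 of 12; camera adjusted p = 0.0409) had an adjusted p = 0.627, 0.442 and 0.442 with an estimated correlation, 0.0872, 0.0861 and 0.0872 with the spike-in set as a block, and 0.0612 to 0.729 with a replicate or slide block or quantile normalization. With normexp, or in a fit of these groups alone, 0 genes were called. Without LIF 0.2 replicate 3 the adjusted p was 0.345 for Syt17 and 0.112 for Ces2b, and without LIF 10 replicate 3 it was 0.0569 for Syt17. Both groups hold arrays of both spike-in sets, and with the set as a block 2 genes were called, both also without it. The number was 0, 1, 17, 19 and 133 without LIF 0.2 replicate 3, LIF 10 replicate 3, LIF 10 replicate 4, LIF 10 replicate 1 and LIF 0.2 replicate 2.

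The interaction at 1 h asks whether the effect of both cytokines differs from the sum of the single log2 effects, which multiplies folds. The combination gave less than the sum for Egr1 (−2.12 ± 0.29, adjusted p = 0.000357), Fos (−1.72 ± 0.26, adjusted p = 0.000975) and the homeobox gene Hoxc6 (−2.04, adjusted p = 0.00362), and more for the heat shock cochaperone gene Dnajb1 (0.44, adjusted p = 0.0167). A fit of these 4 groups alone called 0 genes, with adjusted p = 0.0994 for Egr1 and Fos, 0.172 for Hoxc6 and 0.336 for Dnajb1. Normexp gave adjusted p = 0.148 for Fos, 0.472 for Hoxc6 and 0.0576 for Dnajb1. The call of Dnajb1 also ended with the spike-in set as a block (adjusted p = 0.0726), and at adjusted p between 0.0515 and 0.0783 without EPO+LIF replicate 3, EPO replicate 1 or 2, LIF 10 replicate 4 or control replicate 1 or 2. Hoxc6 was near background in control and LIF 10, and with these at the lowest signal well above background its value was −2.003, and −1.238 with EPO+LIF arrays so treated too. Cholesterol genes shifted upward, with 0 of 24 called over all genes and 8 up and 0 down adjusted over the list alone (camera adjusted p = 2.15e-08). Upward shifts of the precursor list (0 of 21 called; camera adjusted p = 0.00556) and the stress list (1 up and 0 down of 18; 3 and 0 adjusted over the list alone; camera adjusted p = 0.0479) had an adjusted p = 0.193 and 0.289 with an estimated correlation, and the stress list 0.0599 and 0.0712 with replicate and slide blocks. In all 1 gene was above and 3 were below the sum, 4 with the set as a block (3 in both fits); 66.7% of 9 genes were above with quantile normalization and 75% of 4 with normexp. Without EPO+LIF replicate 4 or 1 the number was 10 or 7.

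**Figure D3:**
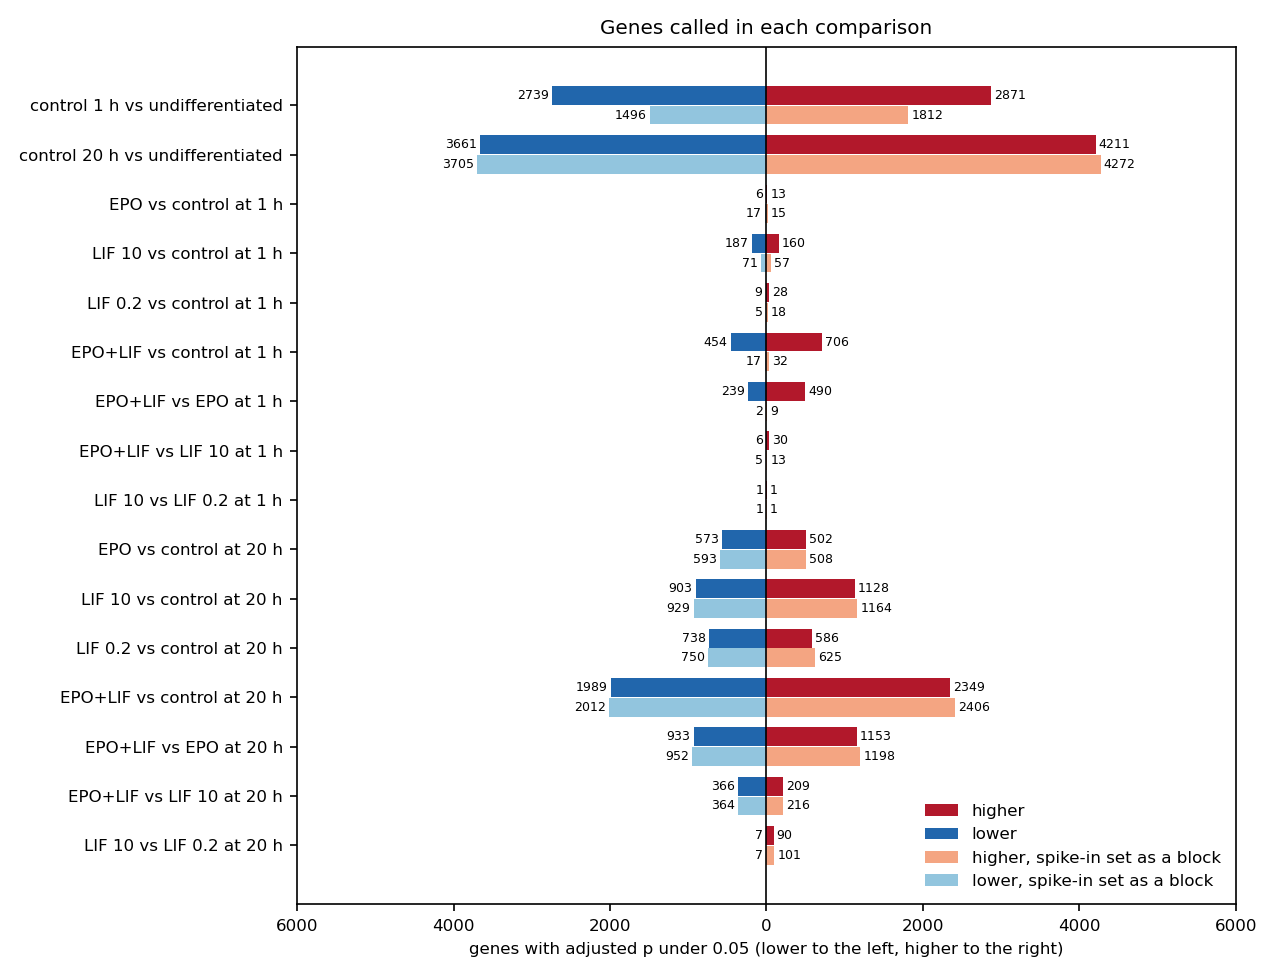
Number of genes called in 16 comparisons of 2 groups of 3 or 4 arrays, higher to the right and lower to the left, with pale bars for the fit with the spike-in set as a block. For EPO+LIF against control, 1160 genes were called at 1 h, 49 with the block, and 4338 at 20 h.

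EPO for 20 h was compared with control for the late response to the receptor (4 arrays each). H19 rose by 12.53 ± 0.45 (adjusted p = 2.5e-20), from −7.15 ± 0.96 (SD), where 1 of 4 control arrays was well above background, to 5.38 ± 0.20 (12.272 with control arrays no lower than the lowest signal well above background, the floor). Its imprinted neighbour Igf2 (1:202906641-202906700), a growth factor, rose by 3.68 ± 0.14 (adjusted p = 1.68e-19). Pmp2 (2:93570068-93570127), a myelin fatty acid-binding protein, rose by 5.24 ± 0.18 (adjusted p = 5.97e-21), and the fatty acid receptor Cd36 (4:13525426-13525485) was at least 108-fold higher. Mag rose by 1.07 ± 0.16 (adjusted p = 2.62e-05), whereas Mbp at 0.13 (adjusted p = 0.881) did not pass the test. The cytokine feedback genes Cish (8:112545330-112545389) and Socs2 rose by 1.75 ± 0.18 (adjusted p = 1.52e-08) and 1.64 (adjusted p = 1.44e-09). Bcl6 fell by 1.34 ± 0.10 (adjusted p = 6.67e-12) and Cryab, a small heat shock protein, by 1.54 ± 0.23 (adjusted p = 2.06e-05).

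Cell cycle genes fell in 28 and rose in 0 of 32 cases with EPO at 20 h (30 and 0 adjusted over the list alone; camera adjusted p = 9.2e-39), with Pcna at −0.51 ± 0.06 (adjusted p = 1.04e-07) and Mcm7, a replicative helicase subunit, at −0.47 (adjusted p = 2.47e-06). Interferon response genes rose in 3 and fell in 0 of 13 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00774). JAK-STAT feedback genes rose in 5 and fell in 1 of 25 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0121; adjusted p = 0.178 with an estimated correlation). The Schwann cell and fibroblast list had 1 gene up, Pmp2, and 1 down of 7 in both counts (camera adjusted p = 1.41e-06; adjusted p = 0.178 with an estimated correlation). Myelin genes rose in 4 and fell in 1 of 19 (6 and 3 adjusted over the list alone), with a camera adjusted p of 0.0843. The astrocyte list had 2 up and 1 down of 13, the immediate early list 4 up and 1 down of 27, and the precursor list 3 up and 0 down of 21, with camera adjusted p of 0.0843, 0.105 and 0.115. Over all genes 502 rose and 573 fell, while 92 of the 100 changes of at least 2-fold were rises. Groups did not overlap for 17.2% of all genes (2.86% by chance), 973 called ones among them. With the slide as a block 1188 were called. Leaving out the 2 arrays farthest out on the second principal component, undifferentiated replicate 3 and EPO+LIF at 1 h replicate 2, called 1945.

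LIF 10 for 20 h was compared with control for the late response to LIF (3 and 4 arrays). Gfap (10:92060835-92060894), the intermediate filament of astrocytes, was at least 49.4-fold higher (adjusted p = 2.42e-14), and Vim, another intermediate filament, rose by 2.06 ± 0.12 (adjusted p = 1.22e-14). H19, well above background on 1 of 4 control arrays, rose by 10.699 ± 0.485 (adjusted p = 1.62e-17; 10.44 with control at the floor). The integrin gene Itga9 rose by 5.77 ± 0.25, Bcl3 by 4.90 ± 0.47 (adjusted p = 1.46e-09), the chemokine gene Ccl20 by 4.13 ± 0.24 (adjusted p = 6.99e-15) and Fos by 3.65 ± 0.19 (adjusted p = 1.21e-15). Socs3 rose by 1.04 ± 0.23 (adjusted p = 0.00112). Mbp at −0.31 (adjusted p = 0.295) and Mag at 0.14 (adjusted p = 0.784) did not pass the test. Cryab fell by 2.13 ± 0.25.

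Under LIF 10 at 20 h, cell cycle genes rose in 0 and fell in 30 of 32 cases (0 and 32 adjusted over the list alone; camera adjusted p = 4.61e-44), Pcna by −0.67 (adjusted p = 5.81e-10). Of the JAK-STAT feedback list, 13 genes rose and 0 fell of 25 (also adjusted over the list alone; camera adjusted p = 5.55e-11). Acute phase and cytokine genes did so in 5 and 0 of 8 (7 and 0 adjusted over the list alone; camera adjusted p = 1.34e-10). Rises and falls numbered 4 and 1 of 13 astrocyte genes (also adjusted over the list alone; camera adjusted p = 2.06e-05) and 6 and 0 of 13 interferon genes (7 and 0 adjusted over the list alone; camera adjusted p = 0.000751). Of the immediate early list, 8 genes rose and 0 fell of 27 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00285; adjusted p = 0.161 with an estimated correlation). Myelin genes rose in 4 and fell in 4 of 19 (5 and 4 adjusted over the list alone), with a camera adjusted p of 0.851. Genes that rose numbered 1128 and those that fell 903, and groups did not overlap for 33.5% of all genes (5.71% by chance), 1976 called ones among them. With the slide as a block 2152 genes were called, in a fit of these groups alone 3223, and without the 2 arrays farthest out on the second principal component 3388.

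LIF 0.2 for 20 h (3 and 4 arrays) raised H19 by 10.436 (10.177 with control at the floor), Itga9 by 4.56, Bcl3 by 3.84, Fos by 3.01 and the transcription factor Stat3, which LIF signalling activates, by 1.63. Gfap was at least 9.09-fold higher (adjusted p = 1.93e-08; log2 1.809 with the mean of its probes) and Vim rose by 1.30. Socs3 had a fold of 0.67 (adjusted p = 0.0654), and Mag one of 0.61 ± 0.18 (adjusted p = 0.0254), the latter one of 0.34 (adjusted p = 0.394) without LIF 0.2 replicate 4 and of 0.94 (adjusted p = 9.57e-05) without replicate 2. The adjusted p of Mag was 0.131 without LIF 0.2 replicate 3, 0.0885 and 0.0506 without control replicates 2 and 1, and 0.167 in a fit of these groups alone. Of the cell cycle list, 0 genes rose and 29 fell of 32 (0 and 32 adjusted over the list alone; camera adjusted p = 7.54e-56), Mki67, a marker of proliferating cells, by −1.01 (adjusted p = 2.27e-08). JAK-STAT feedback genes rose in 9 and fell in 0 of 25 (10 and 0 adjusted over the list alone; camera adjusted p = 1.93e-09). Acute phase genes did so in 3 and 0 of 8 (4 and 0 adjusted over the list alone; camera adjusted p = 0.000251). The counts were 3 and 0 of 13 for interferon genes (also adjusted over the list alone; camera adjusted p = 0.00119) and 3 and 1 of 13 for astrocyte genes (also adjusted over the list alone; camera adjusted p = 0.00591).

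With the lower LIF dose at 20 h, the hypoxia list had 3 genes up and 0 down of 18 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00672) and the immediate early list 5 up and 2 down of 27 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00511), with adjusted p = 0.136 and 0.173 with an estimated correlation. Over all genes 586 rose and 738 fell, and 1283 of them were among the 31.5% of all genes without overlap between the groups (5.71% by chance). A slide block called 1208. A fit of these groups alone called 2492, leaving out the 2 arrays farthest out on the second principal component 2372, and leaving out LIF 0.2 replicate 4 called 867.

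EPO+LIF for 20 h was compared with control for the late response to both cytokines (4 arrays each). H19 rose by 13.56 ± 0.45 (adjusted p = 1.61e-21; 13.303 with control at the floor). Igf2 rose by 4.64 ± 0.14 (adjusted p = 1.64e-22) and Pmp2 by 4.08 ± 0.18 (adjusted p = 1.79e-18), and Gfap was at least 92.8-fold higher (adjusted p = 2.19e-17). Vim rose by 2.13 ± 0.11 (adjusted p = 1.93e-16), Fos by 3.86 ± 0.18 and Itga9 by 5.99 ± 0.23. The feedback genes Socs2, Cish and Socs3 rose by 1.95 ± 0.15 (adjusted p = 2.39e-12), 1.76 ± 0.18 (adjusted p = 1.55e-09) and 1.21 ± 0.21 (adjusted p = 2.69e-05). Mag rose by 0.57 ± 0.16 (adjusted p = 0.00804, on 3 of 4 slides), and Mbp at −0.27 (adjusted p = 0.219) did not pass the test.

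All 32 cell cycle genes fell with EPO+LIF at 20 h (also adjusted over the list alone; camera adjusted p = 2.27e-76), with Mki67 at −1.94 ± 0.10 (adjusted p = 5.75e-17) and Pcna at −1.25 ± 0.06 (adjusted p = 5.91e-18). Rises and falls numbered 14 and 2 of 25 JAK-STAT feedback genes (camera adjusted p = 9.17e-08), 7 and 0 of 8 acute phase genes (camera adjusted p = 2.27e-06) and 9 and 0 of 13 interferon genes (camera adjusted p = 0.000707), each also adjusted over the list alone, and 7 and 1 of 13 astrocyte genes (8 and 1 adjusted over the list alone; camera adjusted p = 6.16e-05). Immediate early genes rose in 13 and fell in 4 of 27 (also adjusted over the list alone; camera adjusted p = 0.00554), and the Schwann cell and fibroblast list had 2 up and 0 down of 7 in both counts (camera adjusted p = 0.0108). Both lists had an adjusted p = 0.127 with an estimated correlation. Myelin genes rose in 6 and fell in 4 of 19 (7 and 4 adjusted over the list alone; camera adjusted p = 0.793), hypoxia genes rose in 7 and fell in 0 of 18 (camera adjusted p = 0.174), and neuron genes rose in 6 and fell in 1 of 12 (camera adjusted p = 0.083). In total 2349 genes rose and 1989 fell, 800 of them at least 2-fold, and groups did not overlap for 42.9% of all genes (2.86% by chance), 4093 called ones among them. The genes named as changed other than Mag moved 1 way on 4 of 4 slides. With the slide as a block 4643 were called, and in a fit of these groups alone 6631.

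Adding LIF to EPO for 20 h, EPO+LIF against EPO alone (4 arrays each), raised Gfap at least 79.2-fold (adjusted p = 1.35e-16), Itga9 by 4.46, Bcl3 by 4.38 and Vim by 2.15. Cd36 fell by 1.47 and Pmp2 by 1.16 (adjusted p = 8.55e-06). Mag fell by 0.50 ± 0.16 (adjusted p = 0.0372). The adjusted p of Mag was 0.196 and 0.0512 without EPO+LIF replicates 3 and 1, 0.12, 0.0847 and 0.078 without EPO replicates 1, 3 and 4, 0.0536 in a fit of these groups alone and 0.0653 without the filter on dim probes. Socs3 rose by 0.85 (adjusted p = 0.00387) and Cish differed by 0.01 (adjusted p = 0.998). All 32 cell cycle genes fell (also adjusted over the list alone; camera adjusted p = 4.24e-69). Of the JAK-STAT feedback list, 12 genes rose and 0 fell of 25 (camera adjusted p = 1.67e-09), acute phase genes in 5 and 0 of 8 (camera adjusted p = 7.84e-11), astrocyte genes in 4 and 1 of 13 (camera adjusted p = 5.95e-06) and interferon genes in 6 and 0 of 13 (camera adjusted p = 0.00498), each also adjusted over the list alone.

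In the same comparison immediate early genes rose in 7 and fell in 1 of 27 cases (8 and 1 adjusted over the list alone; camera adjusted p = 0.00498; adjusted p = 0.158 with an estimated correlation), and myelin genes rose in 2 and fell in 5 of 19 (2 and 6 adjusted over the list alone; camera adjusted p = 0.287). Genes that rose with LIF added to EPO numbered 1153 and those that fell 933, 1936 of them without overlap between the groups, as for 24.3% of all genes (2.86% by chance). With the slide as a block 2269 were called, and without the 2 arrays farthest out on the second principal component 3331.

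Adding EPO to LIF 10 for 20 h (4 and 3 arrays) raised Pmp2 by 3.41 ± 0.19 (adjusted p = 1.52e-14), Cish by 1.74 ± 0.20 (adjusted p = 1.57e-07) and Socs2 by 1.25 ± 0.16 (adjusted p = 2.05e-06), and Cd36 was at least 22.8-fold higher. Bcl6 fell by 1.26 ± 0.11 (adjusted p = 5.06e-10). Gfap at 0.91 (adjusted p = 0.222) and Socs3 at 0.16 (adjusted p = 0.984) did not pass the test. Cell cycle genes rose in 0 and fell in 29 of 32 cases (0 and 31 adjusted over the list alone; camera adjusted p = 1.12e-83), Mki67 by −0.96. Astrocyte genes rose in 2 and fell in 1 of 13 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0419; 0.0644 with the slide as a block). Interferon genes rose in 1 and fell in 0 of 13 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0419; adjusted p = 0.0807 with an estimated correlation and 0.0644 with the slide as a block), and the Schwann cell and fibroblast list had 1 up and 1 down of 7 in both counts (camera adjusted p = 0.000327; adjusted p = 0.0842 with an estimated correlation). Some 209 genes rose and 366 fell, 565 of them without overlap between the groups, as for 20.9% of all genes (5.71% by chance), and 607 were called with the slide as a block. Without the 2 arrays farthest out on the second principal component 997 were called.

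LIF 10 against LIF 0.2 at 20 h compared the doses (3 arrays each, with no slide holding both). Gfap rose by 2.44 ± 0.38 (adjusted p = 0.000291), Ccl20 by 1.59 and Vim by 0.76 at the higher dose. Acute phase and cytokine genes rose in 3 and fell in 0 of 8 cases (4 and 0 adjusted over the list alone; camera adjusted p = 2.64e-12), and astrocyte genes in 2 and 0 of 13 (3 and 0 adjusted over the list alone; camera adjusted p = 2.92e-05). JAK-STAT feedback genes rose in 1 and fell in 0 of 25 (2 and 0 adjusted over the list alone; camera adjusted p = 0.00106; adjusted p = 0.168 with an estimated correlation). The cholesterol list (0 of 24 called; camera adjusted p = 2.82e-05) and the hypoxia list (0 of 18 called; camera adjusted p = 0.0128) shifted downward, with adjusted p = 0.0673 and 0.214 with an estimated correlation. Over all genes 90 rose and 7 fell, all 97 without overlap between the groups, as for 16.9% of all genes (10% by chance). With the slide as a block 53 were called, 50 up and 3 down, with normexp 55, and without the 2 arrays farthest out on the second principal component 166. The number was 55, 56, 61 and 44 without LIF 0.2 replicates 3 and 2 and LIF 10 replicates 3 and 1.

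At 20 h EPO+LIF was set against the sum of the single log2 effects. H19 lay below that sum by −9.67 ± 0.66 (adjusted p = 1.98e-11; −9.41 with control at the floor). It rose more with EPO+LIF than with either cytokine alone, and its sum lies above the brightest spike-in, so no opposition is shown. Pmp2 lay below the sum by −1.83 (adjusted p = 0.000132) and the serotonin receptor gene Htr2c, near background in control and LIF 10, by −2.08 (adjusted p = 1.81e-06; −2.91 with these at the floor). The integrin gene Itga8 lay above it by 0.50. Cell cycle genes were called in 0 of 32 cases in both counts with a downward shift of the list (camera adjusted p = 3.76e-09), and precursor genes in 0 of 21 (camera adjusted p = 0.0495; 0.0824, 0.0747 and 0.0519 with replicate, slide and spike-in set blocks), each with an adjusted p = 0.346 with an estimated correlation. Of all genes 5 were above and 25 below the sum. A fit of these 4 groups alone called 49, normexp 18, and a filter asking for all 40 arrays 9.

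**Figure D4:**
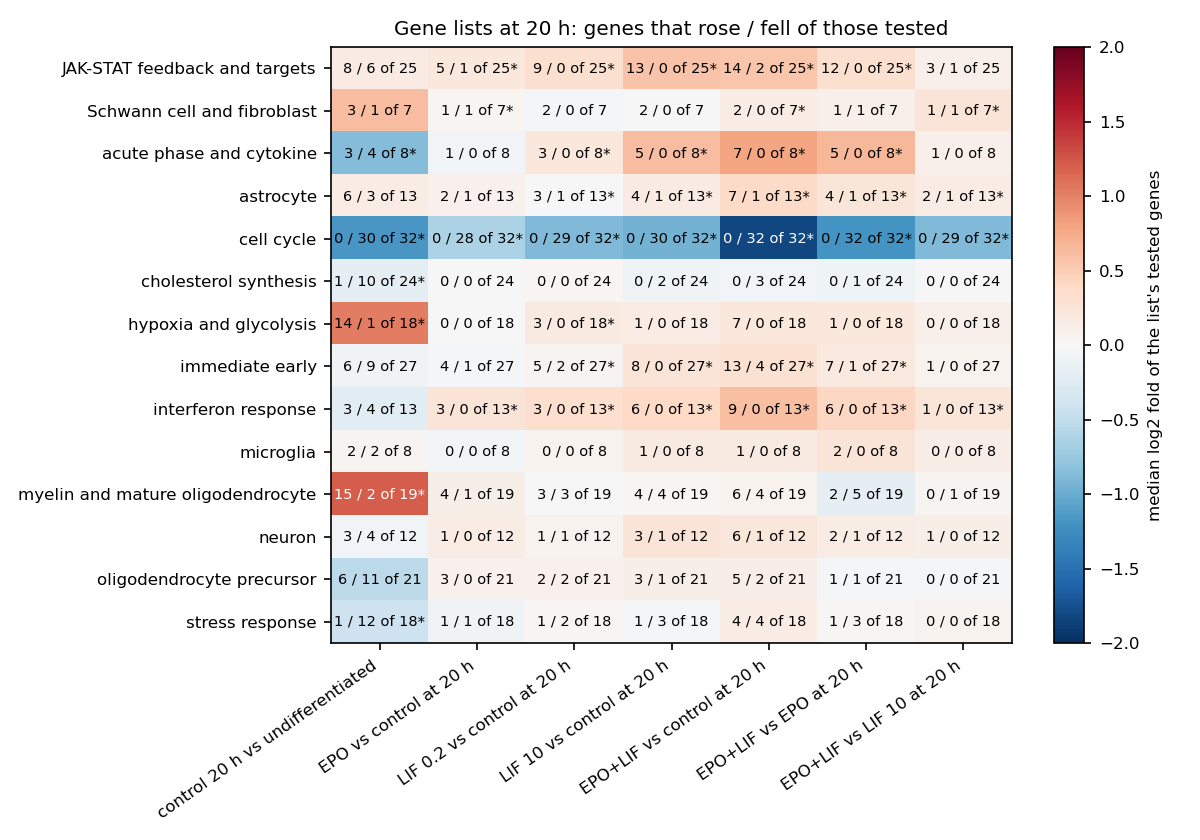
Median log2 fold of 14 gene lists in 7 comparisons at 20 h, as colour, with the number of genes that rose and fell of those tested as text and an asterisk where camera with the preset correlation passed. Cell cycle genes fell in 28 of 32 cases with EPO, 30 with LIF 10 and 32 with EPO+LIF, each against control.

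The EPO effect at 20 h was tested against that at 1 h (4 arrays in each of 4 groups). The effect was larger at 20 h for Pmp2 (4.43), Mag (1.30 ± 0.23, adjusted p = 0.000552) and Socs2 (1.19), and smaller for Egr1 (−4.52, adjusted p = 3.05e-13) and the hyaluronan synthase Has2 (−1.52). Cell cycle genes had a lower effect at 20 h in 20 and a higher one in 0 of 32 cases (28 and 0 adjusted over the list alone; camera adjusted p = 9.7e-30). The immediate early list had 0 genes up and 2 down of 27 (0 and 3 adjusted over the list alone; camera adjusted p = 0.000924; adjusted p = 0.173 with an estimated correlation), and the Schwann cell and fibroblast list 1 and 1 of 7 in both counts (camera adjusted p = 0.000172; adjusted p = 0.139 with an estimated correlation). The EPO effects differed in 352 genes upward and 377 downward, in 1634 genes in a fit of these groups alone and in 1553 without the 2 arrays farthest out on the second principal component.

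The LIF 10 effect at 20 h exceeded that at 1 h for Gfap (4.62 ± 0.48, adjusted p = 2.57e-08), Itga9 (5.78), Emp3 (5.78), Ccl20 (3.85) and Vim (1.89), and was lower for Cryab (−2.02). Gfap was near background in control at both times and with LIF 10 at 1 h, and with these at the lowest signal well above background its value was 5.22. Cell cycle genes had a lower effect at 20 h in 27 and a higher one in 0 of 32 cases (31 and 0 adjusted over the list alone; camera adjusted p = 3.66e-41). Acute phase genes had a higher effect in 4 and a lower one in 0 of 8 (6 and 0 adjusted over the list alone; camera adjusted p = 4.19e-10), and astrocyte genes in 3 and 0 of 13 (also adjusted over the list alone; camera adjusted p = 0.00129). The JAK-STAT list had 6 up and 2 down of 25 in both counts (camera adjusted p = 0.0224; adjusted p = 0.298 with an estimated correlation). At 1 h, 4 of 4 control and 2 of 4 LIF 10 arrays are in the low-slope set with raised keratinocyte transcripts. The effects differed in 641 genes upward and 643 downward (1126 genes with the set as a block), in 2239 genes in a fit of these groups alone and in 2431 without the 2 arrays farthest out on the second principal component.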

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

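In this part, the tests of keratinocytes in the cultures, of treatment or time and of the spike-in set, and the fits with the spike-in set as a block, were chosen only after the result was seen.

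Spike-in RNA, which belongs to no comparison, drew attention as a signal outside the main measurement. On the 12 low-slope arrays the spike-in E1A_r60_a104, taken over the 3 brightest spike-ins, was 273.6-fold higher than on the 28 others, and 11 of 31 keratinocyte transcripts, from a list written after the pattern was seen, were raised by more than 2 log2 units. The spike-in value restates the slope by which the arrays were parted. Keratinocytes in the cultures as the only source are argued against by Sfn, abundant in these cells, which differed by 0.28. Krt5 (0.58) and Krt14 (−0.43) were well above background on 0 and 2 of the 12 arrays, so their probes were not shown to work. The highest of these 3 lay at least 2.236 log2 units below the mean of 5 raised transcripts, but levels of different probes cannot be compared. Treatment or time is argued against by a gap of 4.741 log2 units between low-slope and high-slope arrays of the same LIF groups. RNA that came in with another spike-in mix during labelling or hybridisation may be a source and stays open: over the 12 arrays the raised transcripts and the spike-in excess had a Pearson r of −0.013 (permutation p = 0.966, Spearman rho −0.021, permutation p = 0.957; r = 0.114 without the 2 farthest arrays). A value so near 0 cannot decide it, because a mix added alike to all 12 arrays would give no relation either.

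For EPO+LIF against control at 1 h, which differ wholly in spike-in set, 1160 genes were called. Over these genes, high-slope and low-slope arrays of the LIF groups at 1 h differed in the direction of the EPO+LIF fold by a median of 0.188, which is 0.399 of the median absolute fold of 0.47, and 91.7% of them went that way, against 70.9% of all genes. With the set as a block 49 genes were called, 41 of the 1160 among them in the same direction. The block may remove too little, as 4 low-slope LIF arrays carry its estimate and 1 of them had a mean of the 5 raised transcripts of −2.746, against −0.128 to 1.378 in control. With the effect of the set taken off a second time, 18 of the 41 kept their direction by over 2 standard errors. Where this shrank the fold, as for Fos (3.396), Egr1 (2.618) and H19 (4.219), it argues against the set as the whole cause. Where it enlarged the fold, as for Tnfrsf12a (1.194), the outcome was fixed. The 23 that did not keep their direction so far stay open as well, Tchh (0.872) and Scel (−0.103), transcripts of the epidermis, among them. For the 1119 not called in both fits the median absolute fold was 0.459 without and 0.263 with the block, at median standard errors of 0.112 and 0.157. The spike-in set may account for a part of these and of the 23, and cannot be told apart from EPO+LIF there, since the value of 0.399 lies between the bounds set for either case.

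Arrays that stood apart from the other 3 of their group were sought in 30 measures of 7 groups of 4 arrays, and 20 of 210 cases were found, where chance gives about 1 in 20. With EPO+LIF at 1 h, replicate 3 had a stress response list mean of 0.491 (others 0.375 to 0.39) and an Mbp level of 1.44 (2.45 to 2.644), and replicate 2 a Cspg4 level of −5.711 (−4.538 to −4.312). With EPO+LIF at 20 h, replicate 3 had a myelin list mean of 0.00 (0.138 to 0.16) and an Mbp level of 6.046 (6.179 to 6.185). With EPO at 1 h, replicate 2 had an astrocyte list mean of 0.401 (0.263 to 0.283) and an Lifr level of −4.714 (−5.658 to −5.51), replicate 1 a cell cycle list mean of 2.737 (2.695 to 2.702) and a myelin list mean of −0.686 (−0.77 to −0.763), and replicate 3 an Il6st level of −0.462 (0.283 to 0.29). With EPO at 20 h, replicate 2 had a myelin list mean of 0.137 (0.274 to 0.289) and a Myrf level of −2.729 (−1.92 to −1.806). With LIF 10 at 1 h, replicate 4 had a hypoxia list mean of 0.293 (0.427 to 0.442), an immediate early list mean of −1.514 (−1.063 to −0.992), a Pdgfra level of 3.297 (3.64 to 3.678) and an Olig2 level of 4.501 (4.306 to 4.322), and replicate 3 an Mbp level of 2.899 (2.578 to 2.63). In control cells, Il6st of replicate 4 at 1 h was at −0.459 (0.233 to 0.323), the immediate early list mean of replicate 2 at 20 h at −1.052 (−1.009 to −1), and Myrf of replicate 1 at 20 h at −2.586 (−2.827 to −2.8).

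Differences between the times drew attention by the test of the difference itself. The EPO effect differed between 20 h and 1 h in 729 genes, with Mag at 1.304 and Cish at 0.915 (adjusted p = 0.0296), and the LIF 10 effect in 1284 genes, with Gfap at 4.619 and Socs3 at −1.014 (adjusted p = 0.0338). The call of Cish ended with quantile normalization (adjusted p = 0.0986) or the mean of its probes (0.0703). That of Socs3 ended with the spike-in set as a block (adjusted p = 0.188). Leaving out some single arrays also ended each (adjusted p up to 0.0869 and 0.0857).

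Chance as the source of the counts was examined by other splits of the same arrays. It is argued against where 1 of all 35 splits (the real one) was as large. This holds for control at 1 h (5610 genes; highest other split 3206) and at 20 h (7872; 5465) against undifferentiated cells. The same holds at 1 h for EPO (19; 0), LIF 10 (347; 63), LIF 0.2 (37; 2) and EPO+LIF (1160; 8) against control and EPO+LIF against EPO (729; 3). At 20 h it holds for LIF 0.2 (1324; 651) against control. It is less firm for EPO (1075; 140) and EPO+LIF (4338; 353), whose replicate numbers nearly pair (lowest 0.089 and 0.098). At 1 of 100 reassignments chance is also argued against for the interaction at 20 h (30; 2). So it is for the time differences of EPO (729; 51) and LIF 10 (1284; 380). For the interaction at 1 h 4 of 100 reassignments were as large (4; 201), which is too near 0.05 to exclude chance firmly. The reassignment with 201 genes points to a structure of the arrays, which the reassignments do not hold fixed, and a fit of these 4 groups alone called 0 genes. Chance cannot be excluded for EPO+LIF against LIF 10 at 1 h, where 5 of 35 splits were as large (36; 943), nor for LIF 10 against LIF 0.2 at 1 h, where 12 of 35 were (2; 635). The highest of these splits put the low-slope LIF 10 arrays on the same side, and all low-slope arrays on the same side, which points to a structure of the arrays along the spike-in set; with the set as a block 18 and 2 genes were called. The 10 splits for LIF 10 against LIF 0.2 at 20 h are too few for a share under 0.05 (97; 0).

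The replicate numbers pair the arrays of 3 other comparisons at 20 h, and there the real split was set against the other splits that part all pairs. The highest of those called 677 genes for LIF 10 against control (real split 2031) and 192 for EPO+LIF against EPO (2086). It called 31 for EPO+LIF against LIF 10 (575). Splits parting fewer pairs reached 1182, 39 and 306. The splits parting all pairs, 8 in each comparison, are too few for a share under 0.05, so chance stays open there. With a replicate block the real counts were 2067, 2184 and 583.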

How the results depend on the processing

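The alternatives with the spike-in set as a block, alone or with the replicate block, with the low-slope or high-slope arrays alone, and without the 2 arrays farthest out on the second principal component were chosen only after the result was seen. Of the 20 counts of called genes, all 20 stayed within 1.5 times with the authors' value table, the mean of a gene's probes and the slide as a random block (consensus correlation 0.0496), and 19 with quantile normalization, 18 with the slide as a fixed block and 17 with normexp. Of 1515 named genes by comparison, 1512 kept direction and side of the threshold with the value table, 1454 with quantile normalization, 1408 with normexp, 1494 with the replicate block, 1474 with the slide block and 1404 with the spike-in set block. Of 170 called genes by comparison with several probes, 164 had all probes in 1 direction and 0 had a probe in the other direction with p under 0.05. Signal over background limits the folds of dim genes, which normexp shrinks by its construction: Cd36 with EPO at 20 h went from 6.98 to 3.52 and Gfap with LIF 10 at 20 h from 5.84 to 2.42. Where nothing else is said, the cause was not tested.

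In 2 cases a called fold took the other sign and was no longer called: Arc, EPO vs control at 20 h, went from −0.398 (adjusted p = 0.0339) to 0.03 (adjusted p = 0.957) with normexp, and Nes, control at 1 h vs undifferentiated, from −0.273 (adjusted p = 0.039) to 0.029 (adjusted p = 0.934) with the mean of the probes. Col1a1, EPO+LIF vs EPO at 1 h, which was not called (0.129, adjusted p = 0.513), was at −0.922 (adjusted p = 0.0274) with the mean of the probes. In a fit of the compared groups alone, which estimates the spread from fewer arrays, counts were 1962 for control at 1 h and 4526 at 20 h vs undifferentiated, 60 for LIF 10, 3 for LIF 0.2 and 415 for EPO+LIF vs control at 1 h, 298 and 1 for EPO+LIF vs EPO and vs LIF 10 at 1 h, 0 for LIF 10 vs LIF 0.2 at 1 h, 0 and 49 for the interactions at 1 h and 20 h, 3223 for LIF 10, 2492 for LIF 0.2 and 6631 for EPO+LIF vs control at 20 h, and 1634 and 2239 for the EPO and LIF 10 time differences. With the spike-in set as a block they were 3308 for control at 1 h vs undifferentiated and, at 1 h, 32 for EPO, 128 for LIF 10, 23 for LIF 0.2 and 49 for EPO+LIF vs control, and 11 and 18 for EPO+LIF vs EPO and vs LIF 10. With that block and the replicate block they were 3536, 46 for EPO, 113 for LIF 10, 37 for EPO+LIF vs control, 9 for EPO+LIF vs EPO and 2 for the interaction at 1 h. Low-slope arrays alone gave 71 genes for LIF 10 and 9 for LIF 0.2 vs control at 1 h, and high-slope arrays alone 10 for EPO+LIF vs LIF 10, from fewer arrays. Without the 2 arrays farthest out they were 33 for EPO, 705 for LIF 10 and 67 for LIF 0.2 vs control, 65 for EPO+LIF vs LIF 10 and 17 for the interaction at 1 h, 1945 for EPO, 3388 for LIF 10 and 2372 for LIF 0.2 vs control, 3331 and 997 for EPO+LIF vs EPO and vs LIF 10 and 166 for LIF 10 vs LIF 0.2 at 20 h, and 1553 and 2431 for the EPO and LIF 10 time differences.

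With the replicate block EPO vs control at 1 h gave 36 genes, and no other gene count moved beyond 1.5 times. The slide as a block gave 53 for EPO vs control at 1 h and 53 for LIF 10 vs LIF 0.2 at 20 h, and quantile normalization 9 for the interaction at 1 h. Without a filter, with more genes tested, the counts were 7 for the interaction, 59 for LIF 0.2 vs control and 8 for LIF 10 vs LIF 0.2, all at 1 h; with a filter asking for all 40 arrays, and fewer genes, they were 2, 215 for LIF 10 vs control and 0 for LIF 10 vs LIF 0.2 at 1 h and 9 for the interaction at 20 h. Normexp gave 0 and 55 for LIF 10 vs LIF 0.2 at 1 h and 20 h and 18 for the interaction at 20 h.

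Leaving out 1 array at a time kept 150 of 181 counts within 1.5 times, and the ranges of the others at 1 h were 10 to 24 for EPO, 193 to 496 for LIF 10, 9 to 56 for LIF 0.2 and 718 to 1446 for EPO+LIF vs control, 462 to 975 and 19 to 69 for EPO+LIF vs EPO and vs LIF 10, 0 to 133 for LIF 10 vs LIF 0.2 and 3 to 10 for the interaction. At 20 h they were 867 to 1224 for LIF 0.2 vs control and 44 to 71 for LIF 10 vs LIF 0.2. Lists passing camera with an estimated correlation numbered 2 for LIF 10, 1 for LIF 0.2, 0 for EPO+LIF vs EPO, 2 for EPO+LIF vs LIF 10, 0 for LIF 10 vs LIF 0.2 and 1 for the interaction at 1 h, 2 for EPO vs control, 2 for EPO+LIF vs LIF 10, 2 for LIF 10 vs LIF 0.2 and 0 for the interaction at 20 h, and 1 for the EPO time difference. With the replicate block 1 list passed for the interaction at 20 h and 0 for LIF 10 vs LIF 0.2 at 1 h. With the slide as a block 1 passed for the interaction and 2 for EPO+LIF vs LIF 10 at 20 h, and 0 for LIF 10 vs LIF 0.2 at 1 h. With quantile normalization 2 passed for EPO vs control and 0 for LIF 10 vs LIF 0.2 at 1 h. With the spike-in set as a block 5 passed for EPO+LIF vs EPO, 4 for EPO+LIF vs control and 0 for LIF 10 vs LIF 0.2 at 1 h, and 1 for the interaction at 20 h.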

Other observations

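Tests in this part were written before the result was seen. The imprinted genes were chosen because H19 and Igf2 stood out, and their standard error was no part of the bound first written.

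Tubb3, a tubulin of neurons, fell by 2.42 ± 0.14 (adjusted p = 1.76e-15) in control cells between the undifferentiated state and 20 h, and at 20 h it was higher than in control with LIF 10 (0.63 ± 0.14, adjusted p = 0.00153) and with EPO+LIF (0.90 ± 0.13, adjusted p = 1.74e-06), on 3 of 3 and 4 of 4 slides. Gad1, which makes the transmitter GABA, rose at 20 h by 1.38 ± 0.24 (adjusted p = 0.000152) with EPO, 1.25 ± 0.26 (adjusted p = 0.00062) with LIF 10 and 3.27 ± 0.24 (adjusted p = 5.88e-13) with EPO+LIF. The neuron list of 12 tested genes had camera adjusted p of 0.105, 0.201 and 0.083 in these comparisons.

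H19 and Igf2, neighbours in an imprinted region, rose together at 20 h with EPO (12.53 ± 0.45, or 12.272 with control at the floor, and 3.68 ± 0.14) and with LIF 10 (10.699 ± 0.485, or 10.44 so treated, and 1.96 ± 0.15), which raised the hypothesis that the imprinted gene network changed as a whole. Of 20 members listed, 9 others were tested, and their median log2 fold was 0.044 with EPO (camera p = 0.0781; p = 0.0961 with an estimated correlation) and −0.013 with LIF 10 (camera p = 0.0628; p = 0.238 with an estimated correlation). With EPO, Cdkn1c rose by 0.80 (adjusted p = 0.000105) and 0 members fell; with LIF 10, Cdkn1c rose by 2.00 (adjusted p = 3.08e-12), Plagl1 by 0.54 (adjusted p = 0.0123) and Gatm by 0.48 (adjusted p = 0.0154). The medians lie under the bound of 0.1 set for a change of the network, which taken alone speaks against it. They do so by less than the standard error over the 9 members (0.099 with EPO and 0.24 with LIF 10). A change of the network may thus be present, and the hypothesis stays open.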
